A study of Danio rerio with 28 samples.

How the data were processed

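RNA was sequenced from whole zebrafish larvae of the AB wild-type strain that had been kept in E3 embryo medium at 28.5 C and exposed from day 1 to day 5 after fertilization. The 28 libraries fall into 7 groups of 4: control, cadmium (Cd) at 2.4, 12 or 24 ug/L, and PCB126, a dioxin-like polychlorinated biphenyl, at 0.08, 0.4 or 0.8 nM. The labels give no separate control group for each chemical, name no vehicle for PCB126, and state neither the clock time nor the order of collection. The control libraries are labelled control, but their column names carry the Cd prefix, as those of the Cd groups do. Whether they were kept alongside the PCB126 groups is not stated, so a difference between the 2 series cannot be told apart from PCB126. Per the labels, RNA was extracted with a column kit, polyadenylated RNA was selected with poly-T beads, and cDNA was primed with random hexamers. The labels name both a directional and a non-directional second strand, so strandedness is unknown here.

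The deposited count table holds raw counts per gene, not normalised, for 38318 genes. The labels name HISAT2 2.0.5 and featureCounts 1.5.0-p3 among the tools and GRCz11 as the genome build. The annotation release is not named. Of the genes, 6417 are loci without an Ensembl identifier, here called unannotated loci, which held 7.71% of all counts. The deposited TPM table (made by the authors by dividing counts by gene length and scaling each library) holds 27475 of these genes. TPM recomputed from the counts and the deposited gene lengths differed from it by a relative difference of at most 5.3e-15. Gene length, in bases (unit other, per the file headers), was used only for this check and for a test of length dependence. Every per-sample column was used.

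Total counts per library ranged from 11893345 to 20770004, with a median of 14251922. Intervals for counts are 95% intervals for counting error only. Reads carry no molecular identifiers, so counting error is a lower limit of the true error.

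Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, estimateDisp, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 25393 genes that passed the filter (99.9% of all counts). A gene was called at an adjusted p below 0.05. All 28 libraries entered a single model with a mean per group and 21 residual degrees of freedom, and every exposed group was compared with the same 4 control libraries. The 9 comparisons were each exposed group against control, the highest against the lowest dose of each chemical, and Cd 24 ug/L against PCB126 0.8 nM. A dose trend was a linear slope on dose, fitted for each chemical in its 12 libraries and the 4 controls. Log2 CPM values, used for camera and the principal components, have a prior count of 2. The edgeR log2 fold changes do not use this prior count. CPM values are counts divided by the library total times its TMM factor, and TPM is as above. Errors of log2 fold changes are standard errors (SE), and errors of CPM are standard deviations (SD) over the 4 libraries of a group. The p-values measure the spread between these samples. Nothing in the labels says whether the 4 libraries of a group came from separate clutches or dishes.

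The design, the 34 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls at the top dose of each chemical, and 4 of each elsewhere, among called genes with a mean log2 CPM of at least 1 and a symbol that is not a clone name (letters followed by at least 4 digits, a point and a digit, or a clone prefix). In these genes all 4 libraries had to lie on the same side of the mean of the other group. The wording fixed beforehand set no lowest number of digits for a clone name. Read that way, it leaves he1.1, xkr8.2 and hsp70.3 out of the largest rises and falls. The rule also named up to 4 members of each list per comparison and 17 genes regardless of their values. Of those 17, ahrra and cyp19a1b matched no symbol, and tshba, vtg1, cyp1b1 and mtbl were below the filter with 147, 36, 9 and 0 counts over all libraries. Genes that the rule did not name are said to have been chosen after their values were seen.

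Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance, were run beside it. The count of members called is given over all genes and adjusted over the list alone.

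The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, a filter at a mean of 10 counts, limma on log2(TPM + 1), a fold threshold of 1.5, a model of only the groups compared, replicate number as a block, and leaving out each library. A further alternative, without control replicate 4 and Cd 2.4 ug/L replicate 3 together (called the 2 divergent libraries), was chosen after seeing the data. No pairing by replicate number was assumed: in no comparison did all 4 libraries with matching numbers deviate together from their groups with r above 0.1. The 2 divergent libraries weigh on these deviations in control and Cd 2.4 ug/L, so weaker pairing is not excluded. Mean r for matching and other numbers was 0.122 and -0.0369 at PCB126 0.8 nM against control, and -0.0463 and 0.142 at Cd 2.4 ug/L. Overlap between the chemicals was set against simulated unchanged groups that share the same controls, and against comparisons with the controls divided between the chemicals.

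The tests were tried on simulated data built from a single mean per gene over all 28 libraries and the spread of the model of all 7 groups. In these data 200 of 25393 genes were changed at Cd 24 ug/L. The changed genes were drawn only from genes with higher counts, so the rates below do not cover genes with low counts. The edgeR test called 26% of genes changed 1.5-fold, 46% of those changed 2-fold, 98% of those raised 4-fold and 92% of those lowered to 0.25 of their level. Unchanged genes made up 5.75% of its calls. DESeq2 called 42%, 60%, 98% and 96%, with 16.9% unchanged genes among its calls, and limma on TPM called 28%, 44%, 98% and 88%, with 5.15%. Camera called a planted list of 30 genes and 0 of the 34 real lists. Simulated genes were drawn independently of each other, so this does not test false calls that come from correlation within a list.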

Results

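Polyadenylated RNA was counted in whole zebrafish larvae exposed for 4 days to cadmium (Cd), a toxic metal, or to PCB126, an agonist of the aryl hydrocarbon receptor (AhR). Each of 7 groups had 4 libraries: control, Cd at 2.4, 12 and 24 ug/L, and PCB126 at 0.08, 0.4 and 0.8 nM. Libraries held 11893345 to 20770004 counts, and group means ran from 13531800 ± 1100000 (SD, n = 4) at PCB126 0.8 nM to 17190700 ± 3738000 (SD, n = 4) at Cd 12 ug/L. Of the genes in the table, 25393 had enough counts to be tested. The series title names endocrine disruption by both chemicals as the subject. Control replicate 4 and Cd 2.4 ug/L replicate 3 stood apart from the other 26 libraries, with TMM factors of 0.646 and 0.687 and ribosomal protein genes taking 11.8% and 12.2% of their counts. The first principal component, with 48.4% of the variance, separated this pair from the rest. For each comparison the number of called genes without this pair is given beside that with all 28 libraries, as an alternative chosen after seeing the data. Called members of the gene lists without this pair are given after each set of lists.

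**Figure D1:**
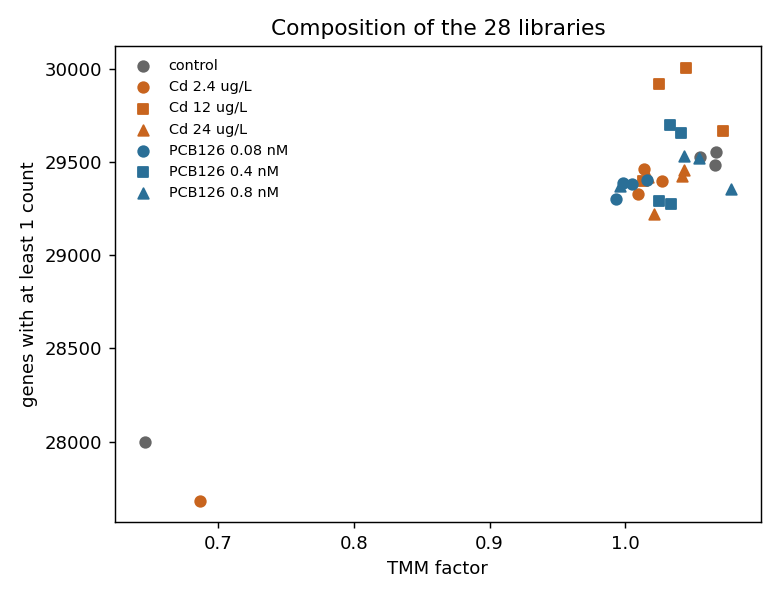
Each point is 1 of the 28 libraries, by its TMM factor (x, no unit) and the number of genes with at least 1 count (y), coloured by chemical with a symbol per dose. Control replicate 4 (0.646, 27999 genes) and Cd 2.4 ug/L replicate 3 (0.687, 27683 genes) lie apart from the other libraries.

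The comparison of PCB126 0.8 nM with control asked what the highest dose of the AhR agonist changed. Xenobiotic-metabolising cytochrome P450 genes rose most. Transcripts of cyp1a (ENSDARG00000098315, chromosome 18, 5588068 to 5598958, GRCz11), the classical AhR target, rose from 43.3 ± 5.50 to 6553 ± 133 CPM (SD, n = 4). This was a log2 fold change of 7.24 ± 0.15 (SE) or 151-fold (edgeR, adjusted p = 4.72e-22). The related P450 genes cyp1c1 and cyp1c2 rose by 5.36 ± 0.10 and 4.90 ± 0.16 on the log2 scale. In the AhR list, 10 of 17 tested members rose and 1 fell (12 and 1 adjusted over the list alone), and camera called it higher (adjusted p = 2.23e-08 with an estimated correlation). Beside the P450 genes, the transcription factor gene foxq1a rose by 3.26 ± 0.21 and the receptor gene ahr2 by 1.23 ± 0.15, while sox9b, a transcription factor gene of cartilage formation, fell by 1.43 on the log2 scale (SE 0.09). Other large rises were in fgf7, a growth factor gene (4.07 ± 0.34), ugt1b1, a glucuronosyltransferase gene (2.78), jac1 (2.64) and ostn (2.55).

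Among the largest falls at PCB126 0.8 nM was he1.1, a hatching enzyme gene, at -6.23 ± 1.14. It had 3 counts over the 4 exposed libraries against 277 in the controls, a ratio of control to exposed of 85.1 (95% counting interval 28.8 to 415). The others the rule named were pbld2 (-2.89), fhl5 (-2.13), the glucokinase gene gck (-1.96), angptl1b (-1.76), the keratin gene krt15 (-1.74), bicdl2 (-1.72), cd74b (-1.71), which encodes the invariant chain of antigen presentation, loxl5b (-1.66) and xkr8.2 (-1.55). The call of pbld2 ended when any of 7 of the 8 libraries was left out (highest adjusted p = 0.0994). That of gck ended without PCB126 0.8 nM replicate 1, 2 or 3 (highest adjusted p = 0.0838) and that of cd74b without control replicate 4 (adjusted p = 0.0558).

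Tissue and pathway lists moved in both directions at PCB126 0.8 nM. In the cartilage and bone list, 11 of 35 members fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation). The cartilage collagen genes col9a1a and col2a1a fell by 0.73 and 0.58 on the log2 scale (SE 0.11 for both), the aggrecan gene acana was at -0.47 ± 0.12, and runx3 rose by 0.48 ± 0.12. Of 42 proliferation genes, 13 fell (25 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation), including the replication helicase gene mcm5 at -0.70 ± 0.14 and mki67 at -0.43 ± 0.09. Of 40 photoreceptor genes, 9 fell (16 lower and 1 higher adjusted over the list alone; adjusted p = 0.194 with an estimated correlation), including the blue cone opsin gene opn1sw2 (-0.65 ± 0.08) and rhodopsin, rho (-0.93 ± 0.22). Of 43 skeletal muscle genes, 6 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Of 27 cardiac muscle genes, 5 fell (9 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation). Among them were the myosin genes myhb at -0.93 ± 0.15 and myh7 at -0.69 ± 0.09.

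Stress, metabolic and immune lists also passed camera at PCB126 0.8 nM. In the Nrf2 list, 7 of 36 members rose (8 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), led by the genes of the antioxidant regulators nfe2l2b (2.53 ± 0.16) and nfe2l2a (0.90 ± 0.07). Of 42 hypoxia genes, 10 rose (10 higher and 3 lower adjusted over the list alone; adjusted p = 0.0635 with an estimated correlation), with epas1a at 0.74 ± 0.09. Of 28 inflammation genes, 7 rose (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.487 with an estimated correlation), including the matrix metalloproteinase genes mmp13a (2.19 ± 0.30) and mmp9 (1.71 ± 0.30). Of 38 fatty acid genes, 3 rose and 1 fell (6 and 3 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation). Of 24 heat shock genes, 6 fell and 1 rose, both over all genes and adjusted over the list alone (adjusted p = 0.293 with an estimated correlation), with the collagen chaperone gene serpinh1b at -1.26 ± 0.23. Camera also called the lens and exocrine pancreas lists lower, with no member called by edgeR in either (0 and 4 lower adjusted over the list alone, adjusted p = 0.487 with an estimated correlation for both). Without the 2 divergent libraries the heat shock, lens and exocrine pancreas calls ended (camera adjusted p = 0.15, 0.131 and 0.22). The call of the inflammation list held in only 4 of the 8 single omissions (camera adjusted p up to 0.15), and those of heat shock, lens and exocrine pancreas in 7.

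With the 2 divergent libraries left out, more members of most lists were called at PCB126 0.8 nM. Higher and lower were 13 and 1 in the AhR list, 2 and 14 in cartilage and bone, 0 and 16 in proliferation, 3 and 17 in photoreceptors, 2 and 9 in skeletal muscle and 0 and 6 in cardiac muscle. They were 20 and 0 in the Nrf2 list, 11 and 2 in hypoxia, 8 and 1 in inflammation, 9 and 3 in fatty acid, 3 and 6 in heat shock, 0 and 0 in lens and 0 and 1 in exocrine pancreas. In the hepatocyte list, 21 of 39 were higher and 0 lower.

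In all, edgeR called 887 genes between PCB126 0.8 nM and control, 514 higher and 373 lower, and 2237 without the 2 divergent libraries (1375 and 862). The count was 544 without PCB126 0.8 nM replicate 2 and 543 without replicate 3. DESeq2 called 1500, a model of only these 8 libraries called 111, and 548 also differed at least 1.5-fold.

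At PCB126 0.08 nM, the lowest dose, cyp1a rose by 3.58 ± 0.12 and cyp1c1 by 2.00 ± 0.09 on the log2 scale against control (n = 4 per group). The rule also named per2, the light-induced clock gene, at 3.01, and cry5, which encodes a light-activated photolyase, at 1.87. The named falls were bicdl2 (-1.38), the transcription factor gene cebpd (-1.27), serpinh1b (-1.20) and the fatty acid elongase gene elovl7b (-1.09). In the AhR list, 3 of 17 members rose (6 adjusted over the list alone; adjusted p = 0.000229 with an estimated correlation). Camera also called 5 lists lower: proliferation, heat shock, cholesterol synthesis, ER stress and estrogen response. Of their 42, 24, 24, 24 and 5 members only 1 fell over all genes, serpinh1b in the heat shock list. Adjusted over the list alone, 11, 6, 0, 4 and 2 fell and 1 heat shock member rose. With an estimated correlation all 5 calls were lost (adjusted p = 0.402, 0.429, 0.473, 0.429 and 0.111). Of these 5, only proliferation was still called without the 2 divergent libraries (camera adjusted p = 0.0103, against 0.282, 0.122, 0.172 and 0.172). Without the pair, edgeR called 8 AhR members higher, 3 proliferation genes lower, 3 heat shock genes higher and 3 lower, 1 ER stress gene lower, and 0 in the cholesterol and estrogen lists. It then called 25 of 41 lens genes higher, against 0 at PCB126 0.8 nM. Also higher were 11 of 27 epidermis, 6 of 19 exocrine pancreas, 9 of 43 skeletal muscle and 8 of 39 hepatocyte genes, with 0 lower in each. The PCB126 0.08 nM libraries were shifted toward the 2 divergent libraries in composition. Ribosomal protein genes took 6.27% to 6.45% of their counts, against 5.99% to 6.03% in control replicates 1 to 3. Their count-weighted median gene length was 2659 to 2750 bases, against 2791 to 2795, and their score on the first principal component -12.8 to 11.2, against -28.4 to -21.0. How much of the count without the pair, or of the rises in the lens and other tissue lists, goes with this shift was not tested. In single omissions the camera calls of the heat shock, cholesterol and ER stress lists held in 7 of 8 and that of the estrogen list in 5.

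The edgeR test called 98 genes at PCB126 0.08 nM, 76 higher and 22 lower, and 2005 without the 2 divergent libraries (914 higher and 1091 lower). The count was 55 without PCB126 0.08 nM replicate 1, 58 without replicate 3 and 55 without replicate 4. The call of cebpd ended without any single PCB126 0.08 nM library or control replicate 4 (highest adjusted p = 0.12) and that of elovl7b without any of these or control replicate 2 (0.136). That of serpinh1b ended without PCB126 0.08 nM replicate 1 or 2 or control replicate 4 (0.0573). DESeq2 called 234, a model of only these 8 libraries 11, and 58 also differed at least 1.5-fold.

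At PCB126 0.4 nM, cyp1a, cyp1c1 and cyp1c2 rose by 6.16 ± 0.14, 4.50 ± 0.10 and 3.48 ± 0.15 on the log2 scale (n = 4 per group), and per2 by 3.30. The named falls were plekhs1 (-2.24), gck (-2.11), the G protein regulator gene rgs2 (-2.06) and irg1l (-1.90). In the AhR list, 8 of 17 members rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 5.17e-08 with an estimated correlation). The Nrf2 list was called higher, with 4 of 36 members up (5 adjusted over the list alone; adjusted p = 0.692 with an estimated correlation). The fatty acid list was called higher with 0 of 38 members called (1 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation). Camera called 7 lists lower. In skeletal muscle 3 of 43 members fell (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). In cardiac muscle 2 of 27 fell (7 adjusted over the list alone; adjusted p = 0.248 with an estimated correlation). In heat shock 2 of 24 fell (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.348 with an estimated correlation). Of 17 p53 targets 1 fell, btg2 at -0.95 ± 0.16 (4 adjusted over the list alone; adjusted p = 0.248 with an estimated correlation). No member of the exocrine pancreas, proliferation or lens lists was called (1, 0 and 0 lower adjusted over the list alone). Their adjusted p with an estimated correlation was 0.484, 0.482 and 0.728. Without the 2 divergent libraries the proliferation and heat shock calls ended (camera adjusted p = 0.268 and 0.205) and the lens list was called higher (0.00201). Called members were then 11 higher and 1 lower in the AhR list, 9 higher in Nrf2, 5 higher in fatty acid, 1 higher and 4 lower in skeletal muscle, and 2 lower in cardiac muscle. In heat shock 2 were higher and 3 lower, in p53 targets 3 were lower, in lens 1 was higher, and 0 were called in exocrine pancreas and proliferation. The camera call of the fatty acid list held in only 4 of the 8 single omissions (adjusted p up to 0.12) and that of the Nrf2 list in 5 (up to 0.315). Those of heat shock, exocrine pancreas and proliferation held in 7.

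At this dose edgeR called 255 genes, 162 higher and 93 lower, and 914 without the 2 divergent libraries (634 and 280). The count was 144 without PCB126 0.4 nM replicate 2 and 165 without replicate 4. The calls of gck and irg1l ended in 5 and 4 of the 8 single omissions (highest adjusted p = 0.1 and 0.0958), among them PCB126 0.4 nM replicates 2, 3 and 4. DESeq2 called 480 and a model of only these 8 libraries 37.

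**Figure D2:**
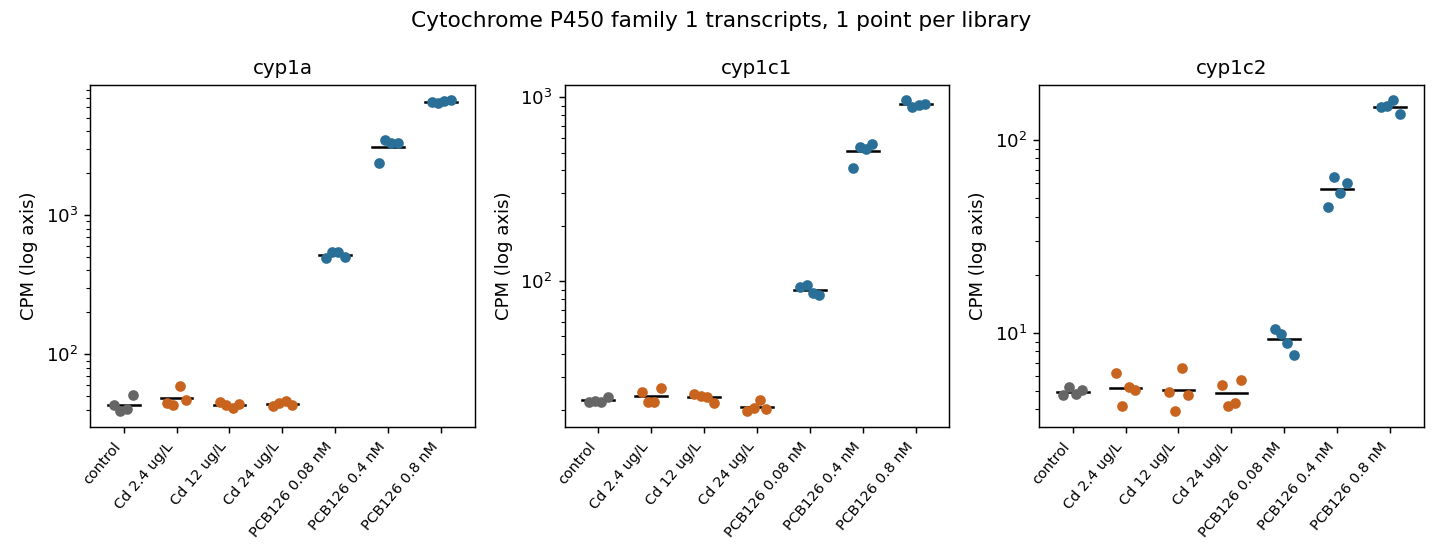
CPM on a log axis (y) of cyp1a, cyp1c1 and cyp1c2 in the 7 groups (x), with 1 point per library and a line at the mean of 4. Mean cyp1a was 43.3 CPM in control, 44.0 at Cd 24 ug/L, and 518, 3105 and 6553 at the rising PCB126 doses.

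The dose trend of PCB126 asked which transcripts followed dose over the 16 libraries of control and PCB126. Among the named genes, linear slopes were highest for cyp1a (7.05 log2 units per nM), cyp1c1 (6.07 per nM), cyp1c2 (6.04) and fgf7 (5.03), and lowest for fhl5 (-2.55), followed by cd74b, angptl1b and krt15. In this trend edgeR called 563 of 24840 genes, 353 rising and 210 falling, and 1577 without control replicate 4, the divergent library among the 16 (860 and 717). The count was 361, 316 and 331 without PCB126 0.8 nM replicates 1, 2 and 3, and DESeq2 called 1156. The trend call of cd74b ended without PCB126 0.8 nM replicate 2 (adjusted p = 0.0737) and that of krt15 without replicate 1, 2 or 3 (highest adjusted p = 0.0742).

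Between PCB126 0.8 and 0.08 nM, a comparison that uses no control library, cyp1c2 was higher at the top dose by 4.00 on the log2 scale, cyp1a by 3.66, fgf7 by 3.55 and cyp1c1 by 3.36. Lower were fhl5 (-1.64), the hyaluronan synthase gene has2 (-1.35), sox9b (-1.32) and loxl5b (-1.31). The AhR list had 10 of 17 members higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 2.68e-09 with an estimated correlation). The Nrf2 list had 7 of 36 higher (14 adjusted over the list alone; adjusted p = 0.0335 with an estimated correlation). The cartilage list had 9 of 35 lower (1 higher and 15 lower adjusted over the list alone; adjusted p = 0.000919 with an estimated correlation). The photoreceptor list had 3 of 40 lower (13 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation). The fatty acid list had 1 of 38 higher (3 adjusted over the list alone; adjusted p = 0.0171 with an estimated correlation). These 5 of the 21 lists that camera called held with an estimated correlation. Among the other 16 was the metallothionein and metal transport list, with 2 of 19 members higher (3 adjusted over the list alone; adjusted p = 0.0514 with an estimated correlation). The myeloid, glia and neuron lists were called lower, with adjusted p = 0.232, 0.0895 and 0.171 with an estimated correlation. When the 2 divergent libraries were left out, edgeR called 13 members higher and 1 lower in the AhR list, 17 and 2 in Nrf2, 1 and 16 in cartilage, 0 and 22 in photoreceptors, 12 and 2 in fatty acid and 3 and 0 in metal transport. It called 3 and 4 in the myeloid list, 0 and 6 in glia and 2 and 10 in neurons. The camera call of the neuron list held in 6 of the 8 single omissions, and those of the other lists named here in all 8. Between these doses edgeR called 260 genes, 169 higher and 91 lower, and 2811 without the 2 divergent libraries, although neither belongs to these groups. The model estimates the spread of each gene over all 7 groups, so the pair enters the spread used here too. Lower without the pair were also 29 of 41 lens genes, 19 of 43 skeletal muscle genes and 13 of 19 exocrine pancreas genes, with 0 higher in each. The groups also differ on the first principal component, which separates the divergent pair (-12.8 to 11.2 at 0.08 nM and -28.9 to -8.47 at 0.8 nM), and how much of these counts goes with that was not tested. Leaving out PCB126 0.08 nM replicate 1, 2, 3 or 4 gave 161, 173, 160 and 166 calls, and leaving out PCB126 0.8 nM replicate 2 or 3 gave 165 and 169. DESeq2 called 552 and a model of only these 8 libraries 1700.

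The comparison of Cd 24 ug/L with control asked what the highest dose of the metal changed. Transcripts of stc1l (ENSDARG00000058476, chromosome 10, 42677891 to 42685512, GRCz11), which encodes the calcium-lowering hormone stanniocalcin, fell by 5.67 on the log2 scale (SE 0.65, edgeR adjusted p = 8.66e-06). They had 6 counts over 4 libraries against 317 in the controls, a ratio of control to exposed of 51.0 (95% counting interval 23.2 to 140). The ionocyte and calcium list it belongs to had 4 of 42 members higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation). In it were the ammonia transporter gene rhcgb at 0.96 ± 0.20 (adjusted p = 0.0605 without Cd 24 ug/L replicate 1) and the ion cotransporter gene slc12a10.2 at 0.54 ± 0.12, a call that ended in 5 of the 8 single omissions (highest adjusted p = 0.13). Of genes chosen after their values were seen, the phosphate hormone gene fgf23 was at -2.54 ± 0.51 (adjusted p = 0.01), a call that ended without Cd 24 ug/L replicate 2 or 4 (highest adjusted p = 0.053). The named rises were per2 (2.82 ± 0.12), the P450 gene cyp2k6 (2.57 ± 0.43), the orphan nuclear receptor gene nr4a3 (1.75 ± 0.21), cry5 (1.56), phka1b (1.55), the urea transporter gene slc14a2 (1.48). Smaller ones were the AP-1 gene fosl1a (1.36), the pyruvate dehydrogenase kinase gene pdk2b (1.32 ± 0.21), lonrf1l (1.28) and the muscle phosphofructokinase gene pfkma (1.25 ± 0.12).

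Besides stc1l, the named falls at Cd 24 ug/L were the calcium-binding protein genes s100a11 (-2.11 ± 0.39) and pvalb8 (-1.57), the secreted phosphoprotein genes scpp9 (-1.89) and scpp1 (-1.22). Others were gck (-1.98 ± 0.48), cd74b (-1.62), serpinh1b (-1.41), the vitamin D 25-hydroxylase gene cyp2r1 (-1.32) and the pyruvate kinase gene pklr (-1.20 ± 0.29, and -0.64 without the 2 divergent libraries). Of these largest rises and falls, the calls of 6 ended when a single library was left out. With the list members and the genes chosen later, 26 of 58 did. The calls of phka1b, gck, cd74b and pklr ended without any of Cd 24 ug/L replicates 1 to 3 or control replicate 4 (highest adjusted p = 0.144, 0.184, 0.143 and 0.188). That of phka1b also ended without control replicate 2 or 3, and that of gck without control replicate 1. The call of scpp9 ended without Cd 24 ug/L replicate 1 (adjusted p = 0.0639) and that of scpp1 without replicate 3 (adjusted p = 0.0514).

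In a cluster of 6 ferritin-family genes on chromosome 3, all but the most abundant were called higher at Cd 24 ug/L, and zgc:198419, zgc:194125 and BX511021.1 at all 3 doses. The most abundant, zgc:92066 (ENSDARG00000031776, 210.9 CPM in control), was at -0.04 and not called (edgeR adjusted p = 0.973), and was called at 0.65 without the 2 divergent libraries (adjusted p = 0.000478). These clone-named genes lie outside the rule and were chosen after their values were seen. The share of each copy is uncertain, since the counting may have split reads between near-identical copies. The gene zgc:198419 (ENSDARG00000076221, 32105175 to 32106672) rose from 18.2 ± 7.54 to 119.6 ± 9.30 CPM (SD, n = 4) at Cd 24 ug/L, by 2.72 ± 0.30 on the log2 scale (adjusted p = 4.8e-06), and by 2.05 ± 0.29 at Cd 2.4 ug/L. Its neighbour zgc:194125 (32125452 to 32127583) rose by 2.73 ± 0.37 at Cd 24 ug/L and was at -1.72, -2.56 and -2.58 at the rising PCB126 doses. Control replicate 4 raised its control mean (61.97 CPM, against 18 to 22.1 in the other 3), and without that library these values were 3.32, -1.12, -1.97 and -1.98. At Cd 2.4 ug/L the call of zgc:194125 (2.07 ± 0.36) ended in 5 of the 8 single omissions, among them Cd 2.4 ug/L replicates 3 and 4 (highest adjusted p = 0.167), as did that of BX511021.1 (2.23, highest adjusted p = 0.192), and at PCB126 0.08 nM the fall of zgc:194125 ended in 5 as well (0.139). The ferritin heavy chain gene fth1a, on chromosome 7, was at -0.42 and not called at Cd 24 ug/L.

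Metallothionein, the usual metal-response protein, gave no call: mt2 was at 1.18 ± 0.39, 0.19 and 0.86 ± 0.39 at the rising Cd doses (edgeR adjusted p = 0.71, 0.86 and 0.36), with 94.2 counts per library on average. Of 19 genes in the metallothionein and metal transport list, edgeR called 0 at any Cd dose, both over all genes and adjusted over the list alone, and camera did not call the list at Cd 24 ug/L (adjusted p = 0.162). At Cd 24 ug/L, 2 of its members were higher and 1 lower without the 2 divergent libraries. The heme oxygenase gene hmox1a was at 0.26 and the heat shock gene hsp70l at 0.58 at Cd 24 ug/L, neither called (adjusted p = 0.55 and 0.37). In the heat shock list, 3 of 24 members rose and 1 fell without a camera call: hsp70.3 (1.25), hsp70.2 (0.87), the co-chaperone gene bag3 (0.70) and serpinh1b (-1.41). The counts were 9 and 3 without the 2 divergent libraries. The call of hsp70.2 ended in 6 of the 8 single omissions (highest adjusted p = 0.125).

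**Figure D3:**
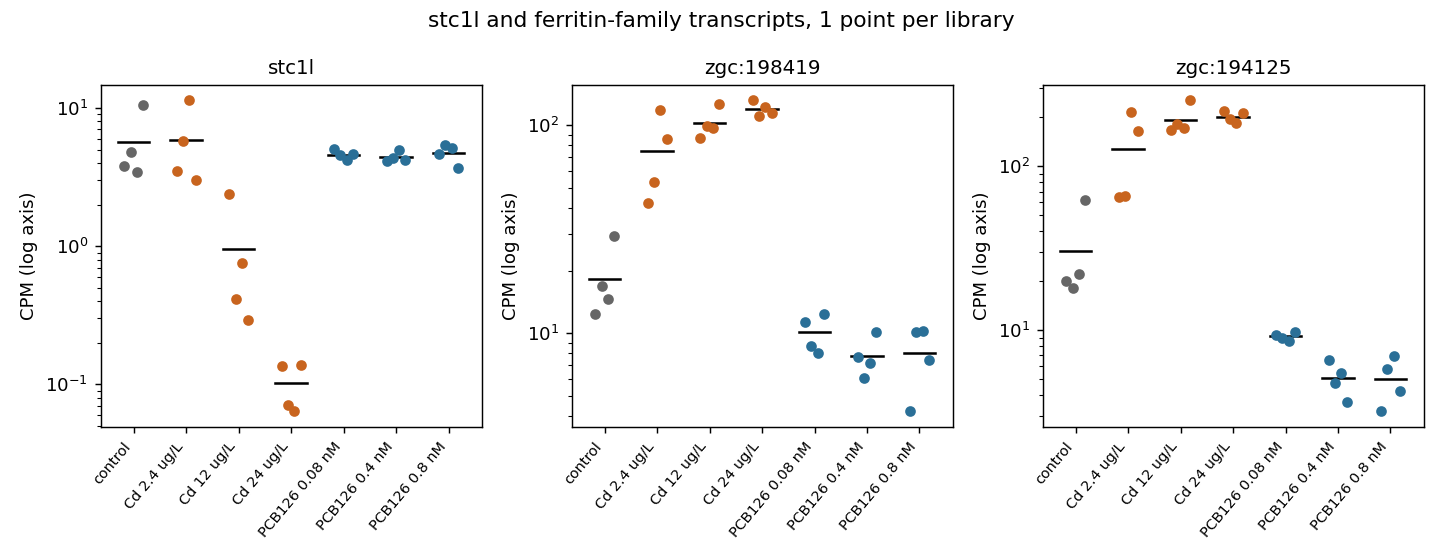
CPM on a log axis (y) of stc1l, zgc:198419 and zgc:194125 in the 7 groups (x), with 1 point per library and a line at the mean of 4. Mean stc1l was 5.65 CPM in control and 0.102 at Cd 24 ug/L, and mean zgc:198419 was 18.2 and 119.6 CPM.

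Camera called 8 lists higher at Cd 24 ug/L, the ionocyte and clock lists among them. Of 42 hypoxia genes, 6 rose (9 adjusted over the list alone; adjusted p = 0.00709 with an estimated correlation). Of these, hif1al rose by 0.64 ± 0.07 on the log2 scale, the glycolytic regulator gene pfkfb3 by 1.17 ± 0.16, epas1a by 0.55 ± 0.09 and vegfaa by 0.48 ± 0.10. Of 38 fatty acid genes, 2 rose (6 adjusted over the list alone; adjusted p = 0.00388 with an estimated correlation), pdk2b and the carnitine palmitoyltransferase gene cpt1b (0.56 ± 0.11; adjusted p = 0.0654 without Cd 24 ug/L replicate 2). The Nrf2 list had 3 of 36 members higher (6 adjusted over the list alone; adjusted p = 0.422 with an estimated correlation). In the glucocorticoid list 1 of 18 rose, the gluconeogenic enzyme gene pck1 at 0.89 (2 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). The inflammation and enterocyte lists had 1 of 28 and 2 of 25 higher (4 and 3 adjusted over the list alone; adjusted p = 0.361 and 0.422 with an estimated correlation). The camera calls of the enterocyte, Nrf2 and ionocyte lists held in only 2, 5 and 6 of the 8 single omissions. With the 2 divergent libraries left out, edgeR called 14 hypoxia, 10 fatty acid, 16 Nrf2, 4 glucocorticoid, 2 inflammation and 8 enterocyte genes, all higher, and 9 ionocyte genes higher and 2 lower. Camera called 4 lists lower: proliferation, lens, exocrine pancreas and hepatocyte proteins. In them edgeR called 1 of 39 hepatocyte genes higher and 1 lower, and 0 in the others. Adjusted over the list alone, 10 proliferation genes and 7 hepatocyte genes fell and 1 hepatocyte gene rose, with 0 in lens and pancreas. With an estimated correlation these 4 calls were lost (adjusted p = 0.299, 0.523, 0.586 and 0.586). The median log2 fold change of the lens list was -0.62, and without the 2 divergent libraries camera no longer called lens, exocrine pancreas or hepatocyte proteins (adjusted p = 0.923, 0.57 and 0.536). These 3 calls held in 7 of the 8 single omissions. Without the pair 5 proliferation genes were lower, 5 hepatocyte genes higher and 3 lower, and 0 were called in lens and exocrine pancreas.

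Altogether, edgeR called 234 genes at Cd 24 ug/L, 189 higher and 45 lower, and 1300 without the 2 divergent libraries (929 and 371). The count was 141, 106 and 149 without Cd 24 ug/L replicates 1, 2 and 3. DESeq2 called 599, edgeR without a filter 141, a model of only these 8 libraries 19, and 135 also differed at least 1.5-fold.

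At Cd 12 ug/L, per2 rose by 2.39, nr4a3 by 1.27 ± 0.21, cry5 by 1.26 ± 0.17 and lonrf1 by 1.07 on the log2 scale. Falls were in stc1l, at -2.62 ± 0.48 (edgeR adjusted p = 0.0092, n = 4 per group), cyp2r1 at -1.19 and serpinh1b at -1.08. The call of stc1l ended without Cd 12 ug/L replicate 2, 3 or 4 (highest adjusted p = 0.0932). Those of the other falls ended too: cyp2r1 without replicate 2 or 4 (0.0735), and serpinh1b without any of the 4 or control replicate 4 (0.252). Camera called the fatty acid list higher, with 1 of 38 members up (3 adjusted over the list alone; adjusted p = 0.009 with an estimated correlation). It also called the hypoxia list higher, with 2 of 42 up (5 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), and the glucocorticoid list with 0 of 18 called (0 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation). Proliferation, hepatocyte proteins and lens were called lower with 0 members called over all genes. Adjusted over the list alone, 1 hepatocyte gene was higher and 0 in the other lists changed, and with an estimated correlation the calls were lost (adjusted p = 0.19, 0.531 and 0.724). The calls of hepatocyte proteins and lens also ended without the 2 divergent libraries (camera adjusted p = 0.356 and 0.322) and held in 7 of the 8 single omissions, and that of hypoxia held in 6. Without the pair 7 fatty acid, 3 hypoxia, 2 glucocorticoid and 1 hepatocyte genes were higher, and 0 were called in proliferation and lens. At Cd 12 ug/L edgeR called 44 genes, 41 higher and 3 lower. The count was 204 without the 2 divergent libraries (180 and 24), and 28 without Cd 12 ug/L replicate 2. DESeq2 called 125 and a model of only these 8 libraries 3.

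At Cd 2.4 ug/L, the lowest dose, the named rises were in clock genes: per2 (1.63 ± 0.12, edgeR adjusted p = 8.71e-09), lonrf1l (0.94 ± 0.07), cry1bb (0.64 ± 0.08) and cry1aa (0.41 ± 0.06). Camera called the photoreceptor, hypoxia, lens and epidermis lists higher and the proliferation list lower, with 0 members of any called by edgeR over all genes. Adjusted over the list alone, 1 hypoxia and 1 epidermis gene rose and 0 in the others changed. With an estimated correlation these 5 calls were lost (adjusted p = 0.661, 0.0872, 0.968, 0.823 and 0.661). They held in 6, 6, 4, 4 and 7 of the 8 single omissions. Leaving out the 2 divergent libraries gave 1 photoreceptor and 1 epidermis gene higher and 0 calls in the others. Cd 2.4 ug/L replicates 1, 2 and 4 were also shifted toward the divergent pair. Ribosomal protein genes took 6.21% to 6.39% of their counts, against 5.99% to 6.03% in control replicates 1 to 3. Their score on the first principal component was -14.8 to -1.11, against -28.4 to -21.0. How far the list calls go with this shift was not tested. At Cd 2.4 ug/L edgeR called 10 genes, all 10 higher and 0 lower (1380 of either direction at an unadjusted p below 0.05). The count was 34 without the 2 divergent libraries (31 and 3), 6 without control replicate 1 or 2, 24 without control replicate 4 and 19 without Cd 2.4 ug/L replicate 1. DESeq2 called 29, and edgeR in a model of only these 8 libraries 0.

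The linear trend over the 16 control and Cd libraries asked which transcripts followed the metal's dose. Among the named genes, transcripts of cyp2k6 and per2 had the highest slopes, 0.09 log2 units per ug/L each, followed by nr4a3 (0.07, edgeR adjusted p = 0.00135) and the vitamin D 24-hydroxylase gene cyp24a1. Transcripts of stc1l fell by 0.24 log2 units per ug/L, followed by scpp9, s100a11 and gck. Over the 16 libraries edgeR called 86 of 24992 genes, 66 rising and 20 falling, and 1335 without the 2 divergent libraries (858 and 477). Single omissions gave between 12 calls (without Cd 24 ug/L replicate 2) and 157 (without Cd 2.4 ug/L replicate 3). The count was 28, 39 and 34 without control replicates 1 to 3, and 57 and 45 without Cd 2.4 ug/L replicates 1 and 2. It was 55, 57, 54 and 53 without the 4 libraries at Cd 12 ug/L, and 21, 19 and 36 without replicates 1, 3 and 4 at Cd 24 ug/L. DESeq2 called 512 and limma on TPM 154. The trend calls of gck and s100a11 each ended in 13 of 16 single omissions (highest adjusted p = 0.163 and 0.153). Those of cyp24a1, scpp9, per2 and cyp2k6 ended in 12, 5, 4 and 2 (0.144, 0.101, 0.0646 and 0.0646).

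Between Cd 24 and 2.4 ug/L, nr4a3 was higher at the top dose by 1.52 on the log2 scale, the heat shock gene hsp70.3 by 1.42, the tyrosinase gene tyr by 1.3 and per2 by 1.19. Lower were stc1l (-5.73), scpp9 (-2.55), s100a11 (-1.90) and scpp1 (-1.51). Of the 12 lists called by camera, only the fatty acid list held with an estimated correlation (0 of 38 members called by edgeR, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0223). In it 7 members were called higher without the 2 divergent libraries. Between the Cd doses edgeR called 132 genes, 60 higher and 72 lower, and 970 without the 2 divergent libraries (526 and 444). The count was 58 and 274 without Cd 2.4 ug/L replicates 3 and 4, and 26, 19, 24 and 35 without Cd 24 ug/L replicates 1 to 4. DESeq2 called 650, edgeR without a filter 70, with a replicate block 82, in a model of only these 8 libraries 0, and 66 also differed at least 1.5-fold. The calls of tyr and s100a11 ended in 4 and 5 of the 8 single omissions, among them Cd 2.4 ug/L replicate 3 and Cd 24 ug/L replicates 1, 2 and 4 (highest adjusted p = 0.107 and 0.116).

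Some clock genes, the light-induced per2 among them, were called higher in every exposed group. Transcripts of per2 (ENSDARG00000034503, chromosome 2, 48309600 to 48375342, GRCz11) had a mean of 26.6 ± 1.67 CPM in control, 82.3 ± 21.4, 139.0 ± 14.9 and 187.9 ± 7.71 at the rising Cd doses, and 214.6 ± 8.72, 261.8 ± 3.90 and 295.6 ± 12.1 at the rising PCB126 doses (SD, n = 4). Its log2 fold change was 3.48 ± 0.13 at PCB126 0.8 nM (adjusted p = 3.7e-16) and 2.82 ± 0.12 at Cd 24 ug/L (adjusted p = 1.11e-13). In the circadian clock list, which had 38 tested members, 4, 6 and 8 rose at the rising Cd doses and 8, 8 and 12 at the rising PCB126 doses, with 0 falls. Adjusted over the list alone, 11, 11, 10, 9, 10 and 13 rose, with 2 falls at PCB126 0.8 nM. With an estimated correlation, camera gave adjusted p = 0.0721, 0.009 and 0.00709 for Cd and 0.00737, 0.00564 and 0.0145 for PCB126, so that the call at Cd 2.4 ug/L was lost. Over all genes but without the 2 divergent libraries, 8, 10, 11, 12, 13 and 18 rose, with 3, 1 and 3 falls at the rising PCB126 doses. Called in all 6 comparisons were per2, lonrf1l, cry1bb and cry1aa, while cry5 was not called at Cd 2.4 ug/L (edgeR adjusted p = 0.143).

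**Figure D4:**
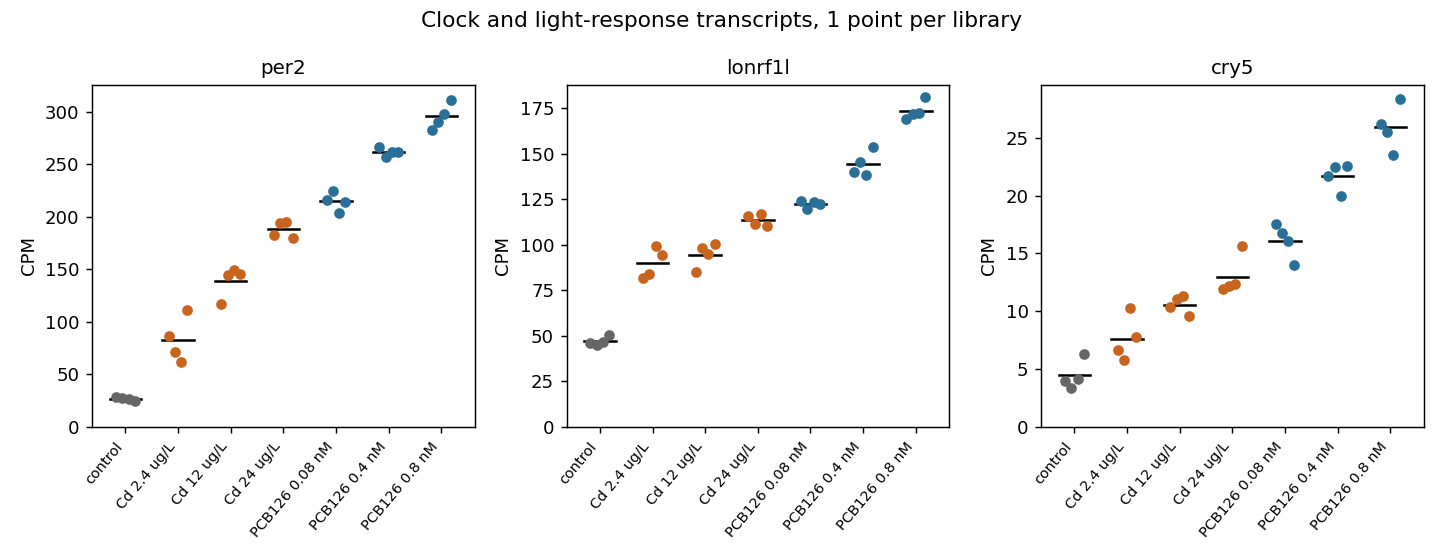
CPM (y) of per2, lonrf1l and cry5 in the 7 groups (x), with 1 point per library and a line at the mean of 4. Mean per2 was 26.6 CPM in control, 187.9 at Cd 24 ug/L and 295.6 at PCB126 0.8 nM.

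The endocrine lists, which concern the subject of the title, held few called genes. In the thyroid axis list at PCB126 0.8 nM, 1 of 17 members rose and 3 fell (1 and 4 adjusted over the list alone), without a camera call (adjusted p = 0.119). The deiodinase gene dio1, which activates thyroid hormone, rose by 1.06 ± 0.21 on the log2 scale (adjusted p = 0.0028, from 12.2 ± 4.26 to 25.5 ± 4.26 CPM, SD, n = 4). The thyroglobulin gene tg was at -0.61 ± 0.14 (adjusted p = 0.013; 0.052 at most without control replicate 4 or PCB126 0.8 nM replicate 2). The calls of dio2 (-1.06 ± 0.28) and pax8 (-0.47 ± 0.13) ended in 6 and 5 of the 8 single omissions (highest adjusted p = 0.154 and 0.123), and that of dio2 also without the 2 divergent libraries. In the steroid and interrenal list, 1 of 16 members fell (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.992). This was hsd11b2, which inactivates cortisol, at -0.83 ± 0.14 at PCB126 0.8 nM and -0.64 at 0.4 nM (adjusted p = 0.0597 without PCB126 0.4 nM replicate 2). The pituitary list had 1 of 11 members lower, the somatolactin gene smtlb at -1.97 ± 0.54 (2 lower adjusted over the list alone; camera adjusted p = 0.252). The call of smtlb ended in 4 of the 8 single omissions (highest adjusted p = 0.212) and without the 2 divergent libraries. At Cd 24 ug/L, 0 members of the thyroid, steroid, pituitary, estrogen and retinoid lists were called by edgeR. Adjusted over the list alone, 3 fell in the thyroid list, 1 fell in the estrogen list and 0 were called in the others. With the 2 divergent libraries left out, 1 thyroid gene was lower, 2 steroid genes were higher and 1 lower, and 1 retinoid gene was higher, with 0 in the pituitary and estrogen lists. At PCB126 0.8 nM without the pair, 1 thyroid gene was higher and 4 lower, 2 steroid genes were higher and 1 lower, and 3 retinoid genes were higher, with 0 in the pituitary and estrogen lists. The steroid transport gene star and the retinoic acid hydroxylase gene cyp26a1 were not called in any comparison with control. The calcium channel gene trpv6 was at -0.53 ± 0.12 at PCB126 0.8 nM (adjusted p = 0.01; 0.0506 without replicate 3) and -0.48 at 0.4 nM (adjusted p = 0.044; up to 0.136 in 7 of 8 single omissions).

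**Figure D5:**
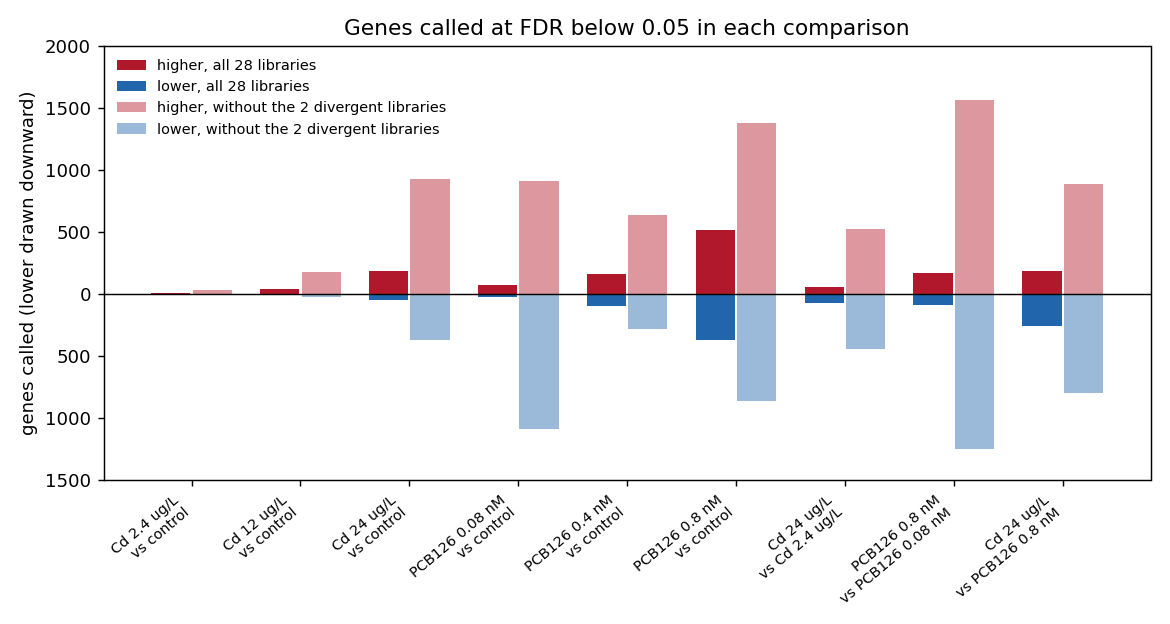
Number of genes called by edgeR (y, falls drawn downward) in the 9 comparisons (x), with solid bars for all 28 libraries and pale bars without the 2 divergent libraries. With all libraries, 234 genes were called at Cd 24 ug/L and 887 at PCB126 0.8 nM; without the pair, 1300 and 2237.

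The direct comparison of Cd 24 ug/L with PCB126 0.8 nM tested whether the 2 top doses differed. Under Cd, cyp1a (-7.22), cyp1c1 (-5.47), stc1l (-5.42) and cyp1c2 (-4.92) were lower, and hsp70.3 (2.23), cyp2k6 (2.01), fhl5 (1.83) and nr4a3 (1.76) were higher. The AhR list was lower under Cd in 11 of 17 members and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 5.12e-10 with an estimated correlation). The cartilage list was higher in 10 of 35 and lower in 2 (18 and 3 adjusted over the list alone; adjusted p = 0.0023 with an estimated correlation). In the heat shock list, 5 of 24 members were higher under Cd (7 adjusted over the list alone; adjusted p = 0.0954 with an estimated correlation), among them hsp70l at 1.09 (adjusted p = 0.033, and up to 0.151 in 6 of 8 single omissions). The clock list had 1 of 38 members higher and 7 lower under Cd (1 and 8 adjusted over the list alone; adjusted p = 0.265 with an estimated correlation). The erythroid list had 1 of 13 lower (1 adjusted over the list alone; adjusted p = 0.0515 with an estimated correlation). Leaving out the 2 divergent libraries gave 1 member higher and 12 lower under Cd in the AhR list, 19 and 3 in cartilage, 9 and 1 in heat shock, 2 and 8 in clock and 0 and 2 in erythroid. Between the chemicals edgeR called 443 genes, 187 higher and 256 lower under Cd, and 1683 without the 2 divergent libraries (886 and 797), neither of which is in these groups. Both still enter the spread per gene, which the model estimates over all groups. A model of only these 8 libraries called 1071.

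Genes called in the same direction by Cd 24 ug/L and PCB126 0.8 nM numbered 127, of which 107 rose and 20 fell, and 6 more were called in opposite directions. Independent lists would share 3.83 rises and 0.661 falls, but lists that use the same controls are not independent. Simulated groups with no change were therefore compared with shared controls. In these runs edgeR called 0 genes for either chemical, so they give no expected number of shared calls. Their log2 fold changes correlated across genes at r = 0.5 on average over 10 runs when controls were drawn too, and at 0.574 (0.562 to 0.583) against the measured controls, where 0.589 was observed (genes are not independent replicates). With controls drawn too and without the 2 divergent libraries, simulated r was 0.563 and the observed r 0.5, so shared controls alone can give a correlation of about this size. The covariance of the log2 fold changes was above that of every run: 0.108 against at most 0.0639 with controls drawn too and 0.0852 with the measured controls, and 0.0793 against at most 0.0538 without the pair. With 2 controls given to each chemical, in 6 runs, 35 to 56 genes were shared, and r lay between -0.026 and 0.059. The covariance then lay between -0.0073 and 0.0161, and no simulated groups were compared with divided controls. Independent lists would share 1.76 to 3.81 rises and 0.369 to 2.5 falls in the runs with divided controls. The lists of these runs have no control library in common, so common control libraries alone do not account for the 35 to 56 genes. The lists still share the spread per gene, so they are not fully independent. Genes of the simulated groups were drawn independently, without a shift in composition common to many genes. The excess covariance can therefore not be assigned to the chemicals. Without the 2 divergent libraries, 574 were shared, 425 rising and 149 falling. The count was 80 without Cd 24 ug/L replicate 1 and 63 without replicate 2. DESeq2 gave 283, edgeR without a filter 74, a model of only the groups compared 7, and a fold threshold of 1.5 gave 54.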

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

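The 3 tests of why control replicate 4 and Cd 2.4 ug/L replicate 3 stand apart were chosen only after that result was seen. Each of 154 groups of 4 libraries (42 for measures of the library, 112 for 16 genes) was tested for a single library far from the other 3. A library stood apart in 19 of them, where chance gives about 1 in 20, and 12 of the 19 were in these 2 libraries.

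Control replicate 4 and Cd 2.4 ug/L replicate 3 each stood apart from the other 3 of their group in the number of genes with a count (27999 and 27683), the TMM factor (0.6459 and 0.6868), the share of the 10 most abundant genes (13.59% and 13.35%), the share of ribosomal protein genes (11.81% and 12.18%) and the count-weighted median gene length (1978 and 1922 bases). Control replicate 4 also stood apart in zgc:194125, a ferritin-family gene (62.0 CPM, against 18 to 22.1), and Cd 2.4 ug/L replicate 3 in hsp70l (4.91 CPM, against 7.77 to 8.21).

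Lower sequencing depth does not account for this pair: 0 of the 2 libraries had a total below the lowest of the other 26. Short genes were higher in both (median log2 deviation from the rest of their group 1.06 and 0.95 for genes of up to 1000 bases, and -0.61 and -0.51 above 8000 bases, over 20153 genes). Spearman rho of deviation with gene length was -0.34 in control replicate 4 and -0.31 in Cd 2.4 ug/L replicate 3. Gene length accounted for only 4.9% of the variance of the deviations of control replicate 4, which goes against loss of long transcripts alone. The deposited length is given per gene and need not be that of the transcripts expressed, so such a loss was not excluded. The deviations of the 2 libraries from their own groups correlated across genes at r = 0.9, which excludes random loss of molecules in each library on its own. What the 2 libraries share (handling, RNA quality or library preparation) is not given by the labels and stays open. They come from different groups, so no biological explanation was tested.

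A single library stood apart in 7 further groups. PCB126 0.8 nM replicate 1 had a total of 11893345 counts, against 13944282 to 14248439 in the other 3. Cd 24 ug/L replicate 4 had 29221 genes with a count, against 29422 to 29460. PCB126 0.4 nM replicate 1 had 5.70% of its counts in ribosomal protein genes, against 5.90% to 5.93%, and cyp1a at 2390 CPM, against 3290 to 3440. In PCB126 0.4 nM replicate 3, cyp26a1 was at 9.92 CPM, against 8.32 to 8.44. In Cd 12 ug/L, per2 was at 117 CPM in replicate 1, against 145 to 149, and zgc:194125 at 251 CPM in replicate 4, against 167 to 181.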

How the results depend on the processing

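The alternative without the 2 divergent libraries, control replicate 4 and Cd 2.4 ug/L replicate 3, was the only one chosen after the data were seen. Turned directions were counted only for genes called in the main edgeR test or in the alternative. So counted over the named genes and comparisons, only the alternative without the 2 divergent libraries turned any, 6 in all. These were crygmx (0.25), crygn2 (0.33), fth1a (0.17) and pklr (0.50) at PCB126 0.08 nM, and zgc:92066 (ENSDARG00000031776) at Cd 12 ug/L (0.66) and Cd 24 ug/L (0.65). Each was called in that alternative. Apart from them, it ended 6 calls and added 299, with 1543 on the same side of the threshold. DESeq2 size factors ended 4 and added 7, the filter at a mean of 10 counts 4 and 6, no filter 45 and 0, DESeq2 0 and 171, limma on TPM 149 and 76, the replicate block 38 and 2, a model of only the groups compared 231 and 87, and single omissions 704 and 106 of all their fits. The cause was not tested. Many small changes are missed: in simulated data 26% of 1.5-fold changes were called.

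Values below follow the order Cd 2.4, Cd 12 and Cd 24 ug/L, then PCB126 0.08, 0.4 and 0.8 nM, each against control, unless named. DESeq2 called 29, 125, 599, 234, 480 and 1500 genes, 650 for Cd 24 against 2.4 ug/L, 552 for PCB126 0.8 against 0.08 nM, 512 and 1156 for the Cd and PCB126 trends, and 283 in the overlap of the top doses. A model of only the groups compared called 0, 3, 19, 11, 37 and 111, then 0, 1700 and 1071 for the comparisons between exposed groups, and 7 in the overlap. It was not run for the trends, where it does not apply. Without the 2 divergent libraries the counts were 34, 204, 1300, 2005, 914 and 2237, then 970, 2811 and 1683, 1335 and 1577 for the trends, and 574 in the overlap. With a fold of at least 1.5 added, 135 were called at Cd 24 ug/L, 58 and 548 at PCB126 0.08 and 0.8 nM, 66 between the Cd doses and 54 in the overlap. Without a filter, 141 were called at Cd 24 ug/L, 70 between the Cd doses and 74 in the overlap. limma on TPM called 6 at Cd 2.4 ug/L and 154 in the Cd trend. The replicate block gave 82 between the Cd doses and 30 in the Cd trend.

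Single omissions gave 6 to 24, 28 to 52, 106 to 244, 55 to 104, 144 to 267 and 543 to 985 genes, 19 to 274 between the Cd doses, 160 to 214 between the PCB126 doses, 316 to 366 between the chemicals, 12 to 157 and 316 to 1577 for the Cd and PCB126 trends, and 63 to 128 in the overlap. Gene lists called were 0, 2, 3, 2, 2 and 4 with an estimated correlation. fry called 1 at Cd 2.4, 7 at Cd 24, 3 at PCB126 0.08 and 7 at 0.4 nM. Without the 2 divergent libraries 15 were called at Cd 12 and 12 at PCB126 0.08 nM. Single omissions gave 4 to 10, 6 to 11, 9 to 18, 5 to 12, 10 to 12 and 13 to 15 lists. The lowest count at Cd 24 ug/L, between the Cd doses, in the Cd trend and in the overlap came without Cd 24 ug/L replicate 2.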

Other observations

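The tests of the ferritin genes, of AhR activation and of light lengthening in the order of the labels, and the splits for Cd 2.4 ug/L and the Cd trend, were chosen only after the results were seen.

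Some genes of vitamin D and phosphate balance, which had no list of their own, were chosen after their values were seen. The gene cyp24a1, which inactivates vitamin D, rose by 2.2 ± 0.42 on the log2 scale at PCB126 0.8 nM (edgeR adjusted p = 0.0021, n = 4 per group) and was at 1.61 and not called at Cd 24 ug/L (adjusted p = 0.065). cyp27b1, which activates vitamin D, was lower at Cd 24 ug/L than at PCB126 0.8 nM, at -1.84 (adjusted p = 0.014, and up to 0.0688 without Cd 24 ug/L replicate 1 or 2), and at -0.82 and not called against control (adjusted p = 0.40). The phosphate transporter gene slc34a2b was at 0.91 at Cd 24 ug/L and not called (adjusted p = 0.23), and the bone matrix gene spp1 was at -1.18. In the myeloid list at PCB126 0.4 nM, mpeg1.2, a macrophage gene (-1.66 ± 0.27), and the antigen presentation gene cd74a (-2.33 ± 0.40) fell, and mpx, a neutrophil gene, rose by 0.73 ± 0.15 (adjusted p up to 0.0781 without PCB126 0.4 nM replicate 2 or 4). Camera did not call this list. Without the 2 divergent libraries 3 of its 21 members were higher and 3 lower. An unannotated locus with a P450 domain rose by 4.52 at PCB126 0.8 nM.

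The light-induced clock gene per2 and the clock list genes lonrf1l, cry1bb and cry1aa were called higher in every exposed group than in control. The DNA repair genes ddb2, xpc and neil1, which light also induces in zebrafish, had a median log2 fold change of 0.83 at PCB126 0.8 nM, in line with more light before collection, but only 0.05, 0.15 and 0.16 at the rising Cd doses. A later clock time cannot be told apart: the difference between positive and negative limb clock genes was -0.02 ± 0.24 (SE, n = 4 per group) at PCB126 0.8 nM, a spread that leaves it open. At the rising Cd doses it was -0.29 ± 0.39, -0.13 ± 0.24 and -0.14 ± 0.24, and at PCB126 0.08 and 0.4 nM -0.35 ± 0.24 and -0.18 ± 0.26. The prediction took a later time to raise this difference, and no rise was seen in any group. The clock time of collection is not given, so the direction that a later time would give is not known. Activation of AhR target genes in every exposed group was excluded by cyp1a, at 0.02 for Cd 24 ug/L. The repair median rose at 6 of the 6 steps from control through the Cd and PCB126 doses in the order of the labels, as did mean per2. Its steps within Cd were small against the range of these genes, -0.21 to 0.18 at Cd 12 ug/L and -0.23 to 0.49 at Cd 24 ug/L. Light that lengthened from group to group may account for the pattern, but the Cd steps cannot decide it. Dose has the same order within each chemical, and the labels give no order of collection. A response to each chemical stays open.

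In that order of the 7 groups, the group means of 53 genes rose and of 27 fell at every step, against 5.04 each for groups in no order. A dose response within each chemical would also raise these numbers, and no other order was counted, so they do not single out this order. lonrf1l, cry1bb, cry1aa, cry5 and cry-dash rose at 6 of 6 steps, ddb2 and xpc at 5, and cry1ab, tefa and neil1 at 4.

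Of 6 ferritin-family genes clustered on chromosome 3, 5 were called higher at Cd 24 ug/L with all libraries, and all 6 without the 2 divergent libraries, where the most abundant, zgc:92066 (ENSDARG00000031776), was at 0.65 (adjusted p = 0.000478). Reads moved between near-identical copies would leave their sum unchanged, but the summed CPM of the 6 copies was 2.26 times that of control (621 ± 37.4 against 274.9 ± 199.7, SD, n = 4). The divergent control library, at 574, lay above the lowest Cd 24 ug/L library, at 571.5, but the other 3 controls had a mean of 175.2 ± 13.0 and the ratio to them was 3.54. This goes against a move of reads among the 6 copies alone. A further gene named zgc:92066 (ENSDARG00000116586) lies beside them and was not summed. It rose too in the Cd trend, by 3.12 on the log2 scale at 24 ug/L. How reads matching several copies were counted is not known here, so a mapping effect was not fully excluded. The divergent control library was excluded as the cause of the 5 calls, since zgc:198419 was at 3.04 without the 2 divergent libraries and the other 4 at 2.46 to 4.06. A response of these genes to Cd is a hypothesis, found and tested on the same data.

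Other divisions of the same 8 libraries went against chance for 8 of the 9 comparisons: in each, 1 of 35 splits, the real one, gave as many genes. This is the lowest share that 35 splits can give. The splits cannot tell exposure from another difference between the groups, such as order of collection. The real counts and the highest of the other splits were 44 and 0 at Cd 12 ug/L, 234 and 1 at Cd 24 ug/L, 98 and 0, 255 and 1, and 887 and 26 at the rising PCB126 doses, 132 and 0 between the Cd doses, 260 and 0 between the PCB126 doses, and 443 and 2 between the chemicals. Chance cannot be excluded for the count at Cd 2.4 ug/L, 10, since 16 of 35 splits gave as many. The highest was 8437, and the 15 splits with both divergent libraries on one side gave 2522 to 8437, a structure of the samples. The real split has 1 of the pair on each side, and the 19 other splits of that form gave 0 genes. For the trends, 3 of 100 drawn splits gave as many as the real 86 for Cd (highest other 3062), and 1 of 100 as many as 563 for PCB126 (highest other 1). Chance was thus unlikely for the PCB126 trend. For the Cd trend the case is weaker, since its splits were chosen after the result was seen and single omissions gave 12 to 157 calls.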
